A study of Mus musculus with 9 samples.

How the data were processed

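Gene expression was measured in 9 mouse brain libraries, 3 per genotype (WT, PG9V and PG9VN), each from a separate mouse aged 7.5 months. The tissue was a dissected piece holding thalamus, hypothalamus and midbrain. Per the labels' protocols, poly(A) RNA was selected from total RNA and sequenced from stranded libraries. The labels give no sex, litter, batch or strain, and replicate numbers were given here in accession order, so they pair nothing.

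The deposited table holds estimated counts per transcript, not divided by length or depth, for 105129 transcripts and 9 mice. Per the submitters' processing notes, the tools named were Trimmomatic 0.33, FastQC, HISAT2 2.0.5 and kallisto 0.43.1, with build mm39. Which of these produced the counts, with which settings and annotation, is not given in the sources used here. That the values are estimated counts was read from the file itself, where 59.6% of values were not whole at a tolerance of 0.001. Each column was matched to its mouse by name, and all 9 were used. Estimated counts share reads among similar transcripts, so near-identical copies are uncertain.

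The test had been planned on gene-level counts. Because the table holds transcripts, the estimated counts of a gene were summed and then rounded to whole numbers. Spreadsheet software had turned 24 symbols into date numbers on 177 transcripts. Of these transcripts 173 were resolved to 26 genes through their identifiers, and 4 were left out. The deposited 33639 symbols became 33641 genes, of which 87 symbols held more than 1 gene identifier. The reference annotation at hand, of the earlier build GRCm38, matched 98.6% of the transcript identifiers. It was used for names and lengths, and no coordinates are given because the builds differ.

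Total counts were 27150500 to 35349217 per library, with a median of 29152418. A floor of 3 counts equals 0.085 to 0.11 CPM, and covers counting error only. Genes with 3 or fewer counts in the libraries of a group are described by CPM, with no fold change.

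Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by genotype, robust quasi-likelihood fit, 1 coefficient per genotype, all 9 libraries). Benjamini-Hochberg adjustment ran over the 17398 genes tested, at a threshold of 0.05. Each pair of genotypes was compared, and a further test covered all 3. CPM values use TMM library sizes. Standard errors of log2 fold changes come from the same fit. On simulated data for PG9VN against WT, with 200 of 17398 genes changed, the test recovered 13 of 67 genes changed 1.5-fold (19.4%), 40 of 67 changed 2-fold (59.7%) and 57 of 66 changed 4-fold (86.4%), with 9 false calls among 126 (7.1%). A planted list of 30 further changed genes, whose calls count as true among the 126, was called, and 0 of 41 unchanged lists were. The data gave 3258 calls in this comparison. The Benjamini-Hochberg cutoff depends on the number of calls, so recovery in the data may differ. The simulated genes were drawn independently, so this does not test list calls for genes that vary together.

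For 42 gene lists, holding 918 symbols of which 888 were tested, members were counted by their calls over all genes and adjusted over the list alone. Some genes, such as Itgax, Ctsb and H2-D1, are in more than 1 list, so results of different lists are not independent. They cover microglia, astrocytes, complement, interferon, antigen presentation, cytokines, lysosome, sphingolipids, neurons, synapse, brain regions, other cell types, mitochondria, stress, lipids, cell cycle and ribosome. Each list was tested in 3 comparisons by camera (limma 3.58.1), adjusted over 126 tests, with a preset correlation of 0.01 and with an estimated correlation. Of 65 calls with the preset value 0 held with an estimated correlation, where the lowest adjusted p was 0.105 and 36 tests had an unadjusted p under 0.05. The self-contained test fry called 50, of which 49 were among the 65. Reactome sets of 10 to 300 tested genes (901 sets, fgsea 1.28.0) were tested likewise. Camera called 422 of 2703 such tests, and 0 with an estimated correlation, where 206 had an unadjusted p under 0.05.

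Named genes followed a fixed rule. It took Grn, and the 12 genes with the largest positive and 12 with the largest negative log2 fold change per comparison among called genes with a mean of at least 2 CPM and no overlap between libraries, leaving out predicted genes. Some items the rule covers, and 1 gene list, are not reported here. It also took up to 4 members with the smallest p in each list in PG9VN against WT, and up to 3 in each of the 10 leading Reactome sets. Such list members could be given in the other comparisons too, and taking the first 2 of each list there was decided after values had been seen. Groups, lists, tests, the naming rule and most alternatives were set before the data were examined.

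Shared controls were addressed with 100 simulations of unchanged groups. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters and thresholds, only the 2 genotypes compared, a covariate for Y-linked counts, 1 surrogate variable (sva 3.50.0) and leaving out each library in turn. Added after seeing the data were a fit of only libraries with Y-linked counts, a fit of transcripts that were not summed, and the leave-one-out counts of each gene list.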

Results

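Brain tissue holding the thalamus, hypothalamus and midbrain was profiled by poly(A)-selected, stranded RNA-seq in 9 untreated mice aged 7.5 months. The mice fell into 3 groups of 3: wild type (WT), PG9V and PG9VN, the last 2 being mutant lines of a study of neuronopathic Gaucher disease, a lysosomal storage disorder. From general knowledge of these lines and not from the labels, both lack progranulin (Grn), a secreted and lysosomal protein. Each library came from a separate mouse. Totals of the estimated counts ranged from 27150500 to 35349217 per library, and 17398 genes were tested. Values below are mean depth-normalized counts (CPM) ± SD over 3 libraries per genotype, log2 fold changes ± SE and Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test.

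The first principal component of log2 CPM held 44.5% of the variance and ran from the WT libraries (-47.7 to -42.5) through PG9V (-9.5 to 8.9) to PG9VN (24.7 to 69.6). PG9VN replicate 2 stood apart on the second component (20.4% of the variance) at 54.8, against -32.6 and -36.8 for PG9VN replicates 1 and 3. In that library the hypothalamic neuropeptide genes averaged -2.47 log2 units against the WT mean, against 0.67 and 0.82 in the other PG9VN libraries, and the cortex and hippocampus markers averaged 1.17, against -0.71 and -0.77. Cerebellum markers averaged 3.40 in PG9V replicate 3. WT replicate 1 and PG9V replicate 2 nearly lacked Y-linked counts, with 13 and 8 counts of Ddx3y against 1173 to 2466 in the remaining libraries, and the labels give no sex. Mitochondrially encoded genes took 6.57% to 6.68% of the counts in WT, 7.49% to 8.86% in PG9V and 7.64% to 7.92% in PG9VN.

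Grn was examined first, as a check of the labels. It fell from 50.1 ± 4.77 CPM in WT to 3.89 ± 1.15 in PG9V (log2 fold change -3.68 ± 0.21, adjusted p = 6.64e-05) and 4.17 ± 0.567 in PG9VN (-3.59 ± 0.21, adjusted p = 2.65e-05), with 78 to 148 counts in each mutant library against 1375 to 1729 in WT. It did not differ between PG9VN and PG9V by that test (0.10 ± 0.21, adjusted p = 0.882).

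**Figure D1:**
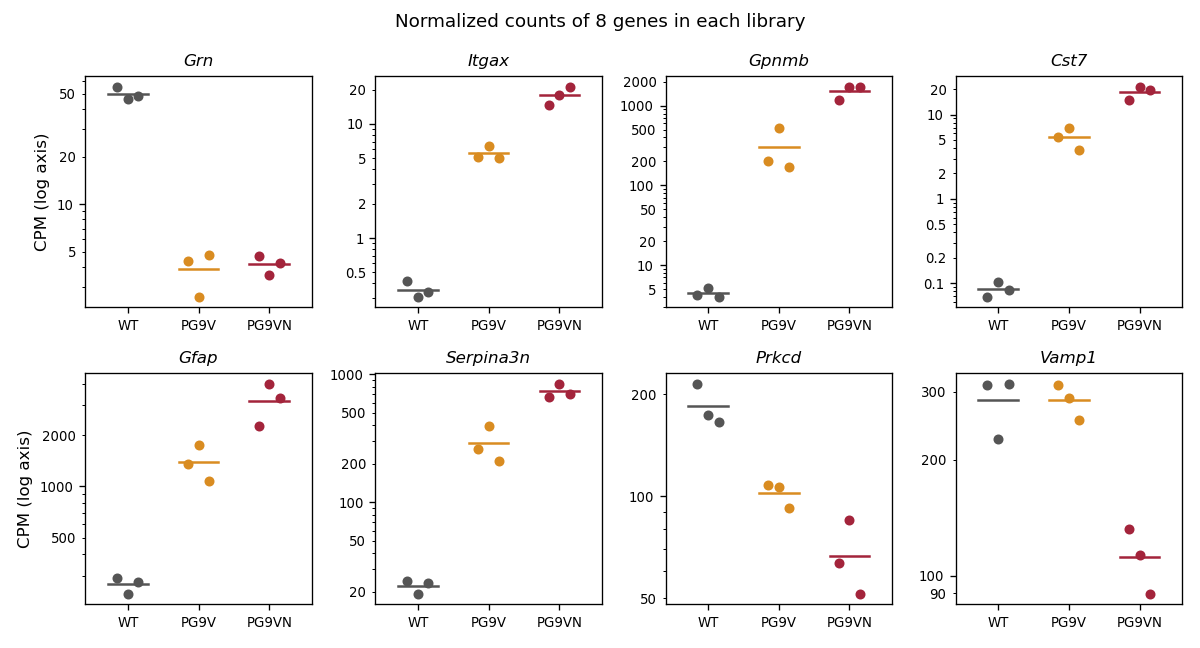
CPM (log axis) of 8 genes in each of the 9 libraries, with points for libraries and a line at each genotype's mean of 3 libraries. Grn is low in both mutant lines, Itgax, Gpnmb, Cst7, Gfap and Serpina3n rise from WT through PG9V to PG9VN, Prkcd is lowest in PG9VN, and Vamp1 is lowest in PG9VN, with means of 285 CPM in both WT and PG9V.

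The comparison of PG9VN with WT asked how the tissue differs between that mutant line and wild type. Most genes of the disease-associated microglia list rose. Gpnmb, a glycoprotein of lipid-laden phagocytes, went from 4.41 ± 0.586 to 1556 ± 323 CPM (log2 fold change 8.46 ± 0.55, adjusted p = 5.00e-05). Clec7a, a phagocytic receptor (6.67 ± 0.40), Lilrb4a, an inhibitory receptor (6.63 ± 0.40), and lysozyme Lyz2 (6.49 ± 0.43) rose from 0.393, 0.734 and 7.99 CPM in WT, and Cst7, a cystatin with few counts in WT, went from 0.0848 ± 0.0162 to 18.6 ± 3.31 CPM. In the list of disease-associated microglia genes, 28 of 30 rose (28 adjusted over the list alone), with a median log2 fold change of 3.22. Of the homeostatic microglia genes, 11 of 18 also rose, among them the receptor Tgfbr1 (0.70 ± 0.08) and Olfml3 (1.19 ± 0.17), and of the markers of microglia and macrophages 12 of 17 rose and 1 fell. Adjusted over the list alone, 11 homeostatic genes were higher and 1 lower, and 12 and 1 of the microglia and macrophage markers. The calls of these lists by camera were lost with an estimated correlation (adjusted p = 0.117, 0.291 and 0.117 with an estimated correlation, in that order).

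Reactive astrocyte, complement, interferon and antigen presentation genes rose in the same comparison. Serpina3n, an astrocyte-secreted protease inhibitor, rose from 22.3 ± 2.68 to 738 ± 96.5 CPM (5.05 ± 0.25, adjusted p = 1.13e-05), and the intermediate filament Gfap from 268 ± 28.9 to 3178 ± 885 CPM (3.57 ± 0.26). Of the reactive astrocyte genes 30 of 33 rose (32 adjusted over the list alone), with a median of 2.56. General astrocyte markers moved less: 7 of 15 rose (7 adjusted over the list alone; 4 without WT replicate 3), with a median of 0.11, Aldh1l1 at 0.65 ± 0.09 and Aqp4 at 0.82 ± 0.13. Complement C3 rose from 3.05 ± 0.759 to 92.3 ± 11.3 CPM (4.92 ± 0.22), and 15 of 22 complement genes were higher and 1 lower (17 and 1 adjusted over the list alone). In the interferon response list 35 of 35 genes rose (35 adjusted over the list alone), with a median of 1.65 and Mx1, an antiviral GTPase, at 1.93 ± 0.17. Of the antigen presentation genes 20 of 24 rose (22 adjusted over the list alone), with the class I heavy chain H2-D1 at 2.41 ± 0.16. Cytokines, chemokines and innate receptors included 24 of 33 higher genes (26 adjusted over the list alone), such as the chemokine Ccl3 (5.23 ± 0.40) and the receptor Tlr13 (2.46 ± 0.16). For reactive astrocytes, astrocyte markers, complement, interferon, antigen presentation and cytokines the adjusted p = 0.105, 0.410, 0.114, 0.126, 0.105 and 0.105 with an estimated correlation.

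Lysosomal genes rose by smaller amounts. Of 54 lysosomal enzymes and membrane proteins 38 were higher in PG9VN (43 adjusted over the list alone) and 0 lower by edgeR, with a median log2 fold change of 0.74 (camera adjusted p = 1.62e-20; adjusted p = 0.117 with an estimated correlation). At an unadjusted p under 0.05 edgeR also gave 0 lower, and DESeq2 called 0 lower. Naglu, which degrades heparan sulfate, rose from 7.58 ± 1.24 to 41.4 ± 4.58 CPM (2.45 ± 0.16, adjusted p = 3.27e-05), and the acid mannosidase Man2b1 from 46.3 ± 2.13 to 118 ± 9.75 (1.35 ± 0.09). Sphingolipid genes went both ways, with 12 of 45 higher and 6 lower (13 and 6 adjusted over the list alone), and that list was not called by camera (adjusted p = 0.294). Its higher members included the hexosaminidase subunit Hexa (1.68 ± 0.15) and the sphingosine phosphate lyase Sgpl1 (1.01 ± 0.10), and its lower members the ganglioside sialyltransferase St8sia1 (-0.90 ± 0.09). The lower count was 3 without WT replicate 1, WT replicate 3 or PG9VN replicate 3. Among lipid transport genes and liver X receptor targets 10 of 22 rose (13 higher and 1 lower adjusted over the list alone; adjusted p = 0.114 with an estimated correlation), including the lipid droplet protein Plin2 (2.04 ± 0.14), the cholesterol hydroxylase Ch25h (3.66 ± 0.29) and Apoe (1.80 ± 0.19).

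Most thalamus markers and some neuron and synapse genes fell in PG9VN. Of 14 thalamus markers 10 fell (12 adjusted over the list alone), with a median log2 fold change of -1.39 (adjusted p = 0.114 with an estimated correlation). The protein kinase Prkcd fell from 185 ± 26.6 to 66.6 ± 16.9 CPM (-1.47 ± 0.18, adjusted p = 6.95e-04), and the nuclear receptor Rora from 129 ± 14.7 to 48.5 ± 8.76 (-1.41 ± 0.17). Of the neuron markers 7 of 21 fell (8 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), led by the neurofilament Nefh (-1.57 ± 0.18), and 12 fell without PG9VN replicate 2. Of 40 synapse genes 13 fell (14 adjusted over the list alone; adjusted p = 0.239 with an estimated correlation), including the vesicle protein Vamp1 (-1.35 ± 0.18) and the GABA receptor subunit Gabrb2 (-1.18 ± 0.18). That count was 8 without WT replicate 1, 7 without WT replicate 3 and 21 without PG9VN replicate 2. The transcription factors Gata3 and Pax7, which mark midbrain neurons, were at 5.17 ± 1.91 and 3.28 ± 1.68 CPM in WT and at 0.602 ± 0.1999 and 0.131 ± 0.0514 in PG9VN (adjusted p = 7.20e-04 and 6.07e-04). Apart from these and Grn, the largest falls by the naming rule were Slc6a4, Abhd12b, Pax5, Tfap2b, Barhl1, Mab21l2, Wnt9b, Glra1 and Shox2. A different cut of the tissue was not tested for them. Myelin genes did not pass the test: by edgeR 0 of 24 were called in either direction (0 adjusted over the list alone), with 2 higher and 1 lower at an unadjusted p under 0.05 and 1 and 1 by DESeq2. Of the 4 region lists outside the thalamus, hypothalamic neuropeptides, cortex and hippocampus, striatum and cerebellum had medians of 0.42, 0.33, 0.34 and -0.43, and PG9VN replicate 2 lay outside all other libraries in each.

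Some cell cycle genes and most ribosomal protein genes were also higher in PG9VN. Of 20 cell cycle genes 9 rose (15 adjusted over the list alone), with the proliferation marker Mki67 at 1.67 ± 0.24 and the cyclin-dependent kinase Cdk1 at 2.24 ± 0.28 (list adjusted p = 0.126 with an estimated correlation). Of 39 cytosolic ribosomal protein genes 26 rose (37 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.488 with an estimated correlation). The ribosomal count was 2, 5 and 3 without WT replicate 1, 2 or 3, and 16 without PG9V replicate 1, and 0 in libraries with Y-linked counts, a set chosen after seeing the data. Without PG9VN replicate 1, 2 or 3 that count was 36, 27 and 21. The ribosomal mean was 0.97 in PG9VN replicate 2, against 0.15 and 0.42 in PG9VN replicates 1 and 3. The deviation of that library from the other PG9VN libraries also ran with transcript length (Spearman rho -0.27 across genes, which are not independent replicates). Its median was 0.31 log2 units for the tenth of genes with the shortest transcripts and -0.27 for the tenth with the longest. It was 0.63 for the ribosomal protein genes and 0.26 for genes with transcripts about as short as theirs. Heat shock protein genes included 5 of 18 that fell (2 higher and 8 lower adjusted over the list alone; adjusted p = 0.491 with an estimated correlation), with Hspa4l at -1.08 ± 0.11, and the count was 3 without WT replicate 1 and 12 without PG9VN replicate 2. The mitochondrially encoded mt-Nd3, a complex I subunit, rose from 242 ± 23.7 to 963 ± 209 CPM (1.99 ± 0.17). The 13 mitochondrially encoded genes had a median log2 fold change of 0.116, and 2 of them were called higher.

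In all, 2002 genes were higher and 1256 lower in PG9VN than in WT, 901 and 173 of them by at least 2-fold. For 6528 genes (37.5%) the libraries of the genotypes did not overlap, where chance gives 10%. The labels give no strain, so a difference of strain background between WT and PG9VN cannot be separated from the genotype in these counts. Without WT replicate 1 the counts were 1299 and 533, without WT replicate 3 they were 1276 and 563, and the lower count was 788 without WT replicate 2, 663 without PG9VN replicate 3 and 2014 without PG9VN replicate 2. Of 901 Reactome sets 158 were higher and 45 lower by camera with a preset correlation, led by peptide chain elongation (50 of 82 genes higher; adjusted p = 0.737 with an estimated correlation) and, as the first set not made up of ribosomal genes, interferon gamma signaling (45 of 80 higher and 1 lower; adjusted p = 0.485 with an estimated correlation).

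**Figure D2:**
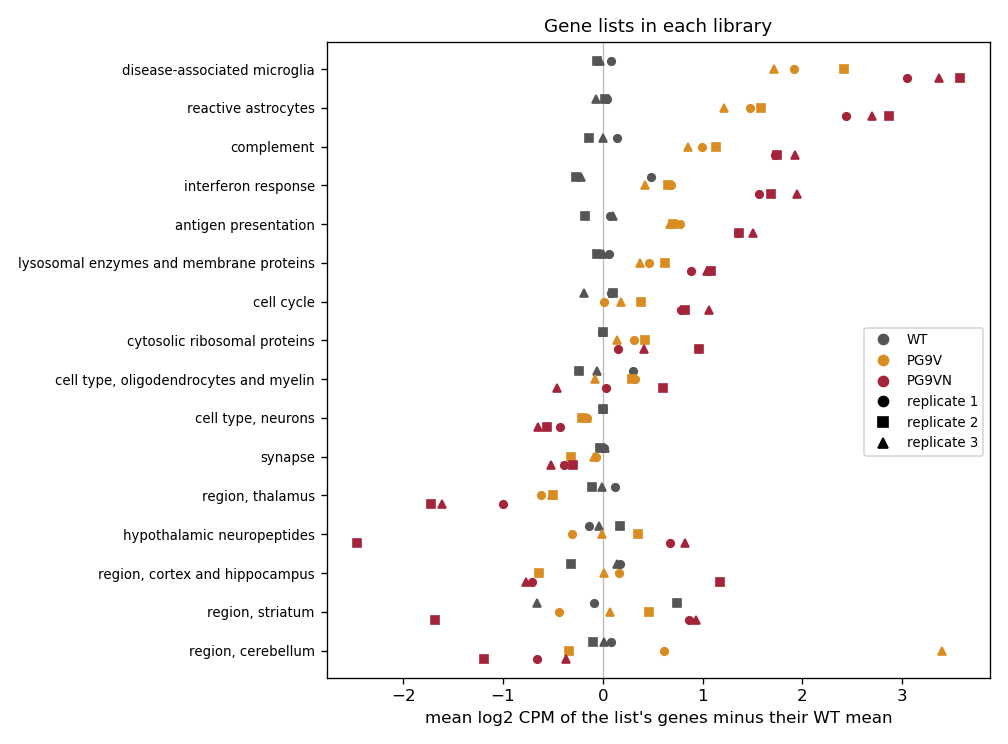
Mean log2 CPM of the genes of 16 lists in each library, minus the WT mean of the same genes, with color for the genotype and the marker shape for the replicate. The PG9VN libraries lie above the PG9V and WT libraries for disease-associated microglia (3.05 to 3.58), and PG9VN replicate 2 lies apart from the other PG9VN libraries in the hypothalamic, cortical and striatal lists.

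PG9V was compared with WT in the same fit. Many microglial and reactive astrocyte genes were higher in PG9V. Gpnmb rose from 4.41 ± 0.586 to 301 ± 201 CPM (6.10 ± 0.50, adjusted p = 6.67e-04), Itgax, an integrin of activated microglia, from 0.352 ± 0.0574 to 5.53 ± 0.783 (3.96 ± 0.22), Lyz2 from 7.99 ± 0.759 to 197 ± 92.8 (4.62 ± 0.40), and C3 from 3.05 ± 0.759 to 25.7 ± 4.45 (3.08 ± 0.20). In astrocyte genes, Serpina3n rose to 288 ± 93.0 CPM (3.69 ± 0.24) and Gfap to 1394 ± 345 (2.38 ± 0.24). Of the disease-associated microglia genes 20 of 30 were higher (27 adjusted over the list alone; 11 without WT replicate 2 or WT replicate 3), with a median of 1.49. Of the reactive astrocyte genes 16 of 33 were higher (25 adjusted over the list alone), with 9, 8 and 7 without WT replicate 1, 2 or 3 and 8 without PG9V replicate 1 or PG9V replicate 2. Complement genes included 10 of 22 higher (13 higher and 1 lower adjusted over the list alone). For these lists adjusted p = 0.114, 0.105 and 0.114 with an estimated correlation.

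Some lysosomal and antigen presentation genes also rose in PG9V, in counts that depended on single libraries. Naglu was at 17.6 ± 2.39 CPM (1.21 ± 0.15, adjusted p = 0.00545), Man2b1 at 79.1 ± 6.80 (0.77 ± 0.09) and H2-D1 at 118 ± 15.9 (1.18 ± 0.16). Of the lysosomal genes 12 of 54 were higher (31 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). That count was 6, 4 and 4 without WT replicate 1, 2 or 3, 6 without PG9V replicate 1, 7 without PG9V replicate 2 and 23 without PG9VN replicate 2. Of the antigen presentation genes 9 of 24 were higher (19 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), and 2 were without WT replicate 1, 2 or 3 or PG9V replicate 1. In the interferon list 2 of 35 genes passed (7 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), with 0 without WT replicate 2, WT replicate 3, any PG9V library, PG9VN replicate 1 or PG9VN replicate 3 and 4 without PG9VN replicate 2, where edgeR gave 11 at an unadjusted p under 0.05 and DESeq2 called 6 with all libraries. Cell cycle genes gave 0 of 20 by edgeR (0 adjusted over the list alone), 3 higher at an unadjusted p under 0.05 and 0 by DESeq2. The mitochondrially encoded mt-Nd3 was at 966 ± 128 CPM (2.0 ± 0.17, adjusted p = 5.89e-04). The 13 mitochondrially encoded genes had a median of 0.296 in PG9V against WT, and 1 was called higher.

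Fewer genes were lower in PG9V. The ribosomal protein gene Rps3a1 was at 28.9 ± 2.03 CPM against 224 ± 6.54 in WT (-2.96 ± 0.16, adjusted p = 6.30e-05), while the near-identical copies Rps3a2 and Rps3a3 went from 0.147 and 0.0713 CPM to 142 ± 9.43 and 45.8 ± 4.90. Counts of these copies are uncertain, since reads can be shared between them, and their sum did not differ (224 ± 6.47 CPM in WT and 216 ± 15.5 in PG9V, log2 fold change -0.05 ± 0.15, adjusted p = 0.924). Nnt, the mitochondrial transhydrogenase, was at 19.7 ± 0.365 CPM against 37.6 ± 2.57 (-0.94 ± 0.10, adjusted p = 0.00154), and Gabra2, a GABA receptor subunit, at 55.6 ± 2.33 against 118 ± 7.61 (-1.09 ± 0.12, adjusted p = 0.00210). Where transcripts were not summed, a setting chosen after seeing the data, the direction of Nnt turned for 1 transcript, ENSMUST00000069902.12, which had 0 counts in every WT library and stood at 5.79 ± 2.37 CPM in PG9V. Its most abundant transcript, ENSMUST00000099149.9, went from 35.8 ± 2.74 to 12.5 ± 2.32 CPM. In PG9VN these Nnt transcripts were at 6.37 ± 1.94 CPM (ENSMUST00000069902.12) and 13 ± 0.451 CPM (ENSMUST00000099149.9). The labels give no strain, so a difference of strain background between WT and the mutant lines cannot be separated from the genotype. This holds for Nnt, Gabra2 and the Rps3a copies, and for every other gene in both comparisons with WT. Of the thalamus markers 2 of 14 fell in PG9V (6 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), with a median of -0.55. These were Synpo2 (-0.84 ± 0.17) and Rgs16 (-0.80 ± 0.15), and neither passed without any 1 of the WT or PG9V libraries (-0.92 to -0.70 for Synpo2, PG9V against WT, and -0.88 to -0.64 for Rgs16, PG9V against WT), while 3, 6 and 4 markers passed without PG9VN replicate 1, 2 or 3.

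In this comparison 281 genes were higher and 26 lower, 193 and 7 of them by at least 2-fold, and 29.7% of genes did not overlap between the genotypes against 10% by chance. The counts were 127 and 8, 102 and 7, and 108 and 10 without WT replicate 1, 2 or 3, 125 and 8 without PG9V replicate 1, 132 and 6 without PG9V replicate 2, and 620 and 269 without PG9VN replicate 2, and 13 were lower without PG9V replicate 3. PG9VN replicate 2 is not in this comparison and acts on these counts only through the fit shared by all 9 libraries. Of 901 Reactome sets 78 were higher and 15 lower, led by translation elongation, called as higher although Rps3a1, which was lower, was the only 1 of its 85 genes called by edgeR (adjusted p = 0.825 with an estimated correlation).

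The direct comparison of PG9VN with PG9V tested whether the mutant lines differ. Many glial and inflammatory genes were higher in PG9VN. Complement C3 was at 92.3 ± 11.3 CPM against 25.7 ± 4.45 (1.84 ± 0.18, adjusted p = 0.00547), Itgax at 18.0 ± 3.31 against 5.53 ± 0.783 (1.70 ± 0.17), the astrocyte gene Aspg at 42.6 ± 3.62 against 16.9 ± 2.27 (1.33 ± 0.12), and Plin2 at 24.2 ± 3.997 against 9.47 ± 0.574 (1.35 ± 0.14). Among lower genes, Pax7 was at 0.131 ± 0.0514 CPM against 4.81 ± 0.973 (adjusted p = 0.00577). The vesicle protein gene Vamp1 was at 112 ± 21.2 CPM against 285 ± 29.8 (-1.35 ± 0.18, adjusted p = 0.00927). The call of Vamp1, PG9VN against PG9V, was lost without PG9V replicate 1 (-1.28) or PG9V replicate 3 (-1.43). The other largest falls by the naming rule were Barhl1, Tfap2b, Gata3, Mab21l1, Abhd12b, Syt2, Tal1, Tcf7l2, Kank4 and Esrrb. A different cut of the tissue was not tested for any of these lower genes. Mt-Nd3 did not differ (-0.01 ± 0.17, adjusted p = 0.994).

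The fixed lists of microglial, astrocyte, immune, lysosomal and cell cycle genes held genes that were higher in PG9VN, in counts that depended on single libraries. Genes higher in PG9VN than in PG9V numbered 23 of 30 for disease-associated microglia (27 adjusted over the list alone), 20 of 33 for reactive astrocytes (29), 15 of 35 for interferon response (35), 12 of 24 for antigen presentation (17), 22 of 54 for lysosomal genes (32 higher and 1 lower) and 4 of 20 for the cell cycle (9), the numbers in parentheses being adjusted over the list alone. In that order the adjusted p = 0.117, 0.105, 0.114, 0.105, 0.118 and 0.114 with an estimated correlation, and the median log2 fold changes were 1.41, 1.27, 1.18, 0.75, 0.34 and 0.76. Without PG9V replicate 1 the counts were 1, 3, 0, 0, 0 and 0, without PG9V replicate 3 they were 2, 4, 0, 0, 0 and 0, and without PG9VN replicate 3 they were 3, 12, 0, 4, 4 and 0. The interferon count was also 5 without PG9V replicate 2, and the cell cycle count 2 without WT replicate 1, WT replicate 3 or PG9V replicate 2. Without PG9V replicate 3 the medians of disease-associated microglia, reactive astrocytes and interferon response were 1.28, 1.18 and 1.15. General astrocyte markers gave 1 of 15 higher (1 higher and 1 lower adjusted over the list alone) with a median of -0.02, and the higher count was 0 to 2 without 1 library. Of the myelin genes 0 of 24 were called by edgeR (0 adjusted over the list alone), 0 had an unadjusted p under 0.05 and 0 were called by DESeq2, with a median of -0.07. Of the thalamus markers 3 of 14 were lower (8 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation), with a median of -0.71. That count was 0 without WT replicate 3, PG9V replicate 1, PG9V replicate 3 or PG9VN replicate 3, 1 without PG9V replicate 2 and 6 without PG9VN replicate 1.

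PG9VN and PG9V differed in 589 genes, 473 higher and 116 lower in PG9VN, and 21.2% of genes did not overlap against 10% by chance. Without PG9V replicate 1 the counts were 17 and 2, without PG9V replicate 3 they were 16 and 3, without PG9VN replicate 3 they were 65 and 14, without PG9V replicate 2 they were 314 and 61, and without PG9VN replicate 2 they were 746 and 374. The lower count was also 58 without WT replicate 1 or WT replicate 3 and 200 without PG9VN replicate 1. Of 901 Reactome sets 104 were higher and 22 lower, led by interferon gamma signaling, with 21 of 80 genes higher (adjusted p = 0.548 with an estimated correlation).

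Both comparisons with WT shared most of the PG9V calls. Of the 281 genes higher in PG9V, 280 were also higher in PG9VN, where independent lists would share 32.3. Simulated unchanged groups against the same kind of shared WT libraries shared 0.05 on average and at most 1 in 100 simulations. Of the 26 lower genes 24 were shared (independent lists 1.88, simulated at most 0). Unchanged groups give hardly any calls, so these simulated overlaps were low in advance and cannot show what shared controls add. Log2 fold changes correlated at 0.775 across genes, which are not independent replicates, against 0.499 in the simulations. Part of the excess in overlap may come from the shared controls, since 3 WT libraries cannot be split. The simulated correlation already holds the shared WT libraries, though in groups without effects. How much of the observed 0.775 they give was not measured. The covariance, to which shared controls add the same amount with or without effects, was 0.301 against a simulated 0.044, a difference of 0.257. Of the 281 genes, 262 had a larger fold change in PG9VN and 183 were called higher in PG9VN than in PG9V, with medians of 2.30 in PG9VN and 1.33 in PG9V. In all, 17, 16 and 65 genes were higher in PG9VN than PG9V without PG9V replicate 1, PG9V replicate 3 or PG9VN replicate 3. The 183 therefore depends on single libraries. The count of genes differing among the 3 genotypes was 2038, with 1114 without WT replicate 1, 1118 without WT replicate 3, 1117 without PG9VN replicate 3 and 3476 without PG9VN replicate 2.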

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

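The tests of the summed Rps3a counts, of the thalamus genes, and of other regions and of the microglial response in PG9VN replicate 2 were chosen only after the result was seen. Those of transcript length and of the other splits of the libraries were chosen before.

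Of the transcripts of Grn, 2 had counts in every mutant library above every WT library, although the gene as a whole fell. In ENSMUST00000125819.8 the lowest mutant value was 0.385 CPM, against 0.283 in WT replicate 2 and a WT mean of 0.094. In ENSMUST00000127530.2 the lowest mutant value was 0.11 CPM against 0 in every WT library. The floor of 3 counts in the WT libraries is 0.085 to 0.105 CPM. Estimated counts share reads among similar transcripts, so such small values are uncertain. The most abundant transcript, ENSMUST00000049460.10, went from a mean of 47.3 CPM in WT to 0.165 in PG9V and 0.291 in PG9VN. These transcripts were not part of the comparisons by gene.

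Rps3a1, Rps3a2 and Rps3a3, a ribosomal protein gene and its near-identical copies, traded counts between genotypes. Reads that moved among the copies, for example because of a variant of the mutant line's strain, would leave their sum in place, and the summed log2 fold change of PG9V against WT was -0.05, with an SE of 0.15. This is consistent with moved reads, a hypothesis found and tested on the same data, but opposite changes in expression that cancel in the sum would give the same value. Both stay open. Rps3a2 stood in PG9VN at 49.5% of its PG9V level.

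The thalamus genes were lower in PG9VN than in WT by a median of -1.39. Dilution of neuronal RNA by glial RNA would lower neuron markers by about as much. The thalamus median minus the neuron median (-0.38) was instead -1.01 (permutation p = 4e-04, two-sided, 14 and 21 genes, which are not independent replicates). Slc17a6 is in both lists. PG9VN replicate 2 alone does not account for it, since the median was -1.29 without that library. Less thalamus in the dissected PG9VN pieces cannot be told apart from a loss in the thalamus itself: of the 4 lists of other regions, 1 had all PG9VN libraries on one side of all WT libraries. The midbrain, also part of the piece, had no region list, and its genes Gata3 and Pax7 fell too. A different cut of the tissue was not tested for these, or for the neuron and synapse genes that fell. A loss of thalamic neurons or of their transcripts with the genotype stays open and was not tested.

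PG9VN replicate 2 stood apart from the other PG9VN libraries. All 4 region lists placed it outside the other 8 libraries, which is consistent with other regions in that dissected piece. Its deviation also ran with transcript length (Spearman rho -0.27 across genes), so a length bias may contribute, although PG9V replicate 2, with a rho of -0.31, did not stand apart in the same way. A microglial response further on in that mouse cannot be told apart from the spread between mice with 3 libraries, as its disease-associated microglia genes lay 0.37 log2 units above the mean of PG9VN replicates 1 and 3. These explanations all stay open.

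For the number of genes differing among the 3 genotypes, 1 of 100 splits of the 9 libraries, the real split, gave 2038 genes and the highest of the others 69, so chance assignment of libraries is excluded at that level. The 10 splits of the 6 libraries of each pair of genotypes are too few for a share under 0.05. In edgeR fits of those 6 libraries the real split gave 1943 genes in PG9VN against WT, 810 in PG9V against WT and 200 in PG9VN against PG9V, and 1 split, the real one, reached each value, the highest other being 0.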

How the results depend on the processing

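The fits of only libraries with Y-linked counts and of transcripts that were not summed were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers, and those used here follow accession order only. Grn kept its direction and call in both mutant lines against WT under each left-out library (-3.85 to -3.46 in PG9V, -3.70 to -3.49 in PG9VN; -0.13 to 0.26 between them).

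Counts of called genes moved more than fold changes. In PG9V against WT, 281 higher and 26 lower became 620 and 269 without PG9VN replicate 2, a library outside that comparison. Those counts therefore depend on the fit shared by all 9 libraries. Which part of the fit acts, and the cause in the other comparisons, were not tested. With DESeq2 the counts were 575 higher and 191 lower in PG9V against WT, 857 and 376 in PG9VN against PG9V, and 3379 genes differing among the 3 genotypes. With only the 2 genotypes compared they were 564 and 246 in PG9V against WT and 177 and 23 in PG9VN against PG9V, and 608 were lower in PG9VN against WT. At an adjusted p of 0.01 they were 1012 genes higher in PG9VN against WT and 369 genes lower in PG9VN against WT, 100 and 7 in PG9V against WT, 46 and 5 in PG9VN against PG9V, and 863 among the 3 genotypes, as a stricter threshold must lower them. With a further minimum of 1.5-fold, 473, 17 and 74 were lower in PG9VN against WT, PG9V against WT and PG9VN against PG9V. The covariate for Y-linked counts gave 16 lower in PG9V against WT and 48 lower in PG9VN against PG9V. With 1 surrogate variable 2375 were lower in PG9VN against WT, 581 higher and 236 lower in PG9V against WT, 893 and 581 in PG9VN against PG9V, and 3921 differed among the 3 genotypes.

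Only libraries with Y-linked counts, 7 in number, gave 1023 higher and 309 lower in PG9VN against WT, 74 and 3 in PG9V against WT, 184 and 16 in PG9VN against PG9V, and 799 genes differing among the 3 genotypes. Transcripts that were not summed gave 1011 and 525, 96 and 15, 2 and 2, and 750, in the same order. Leaving out 1 library gave 1276 to 2365 higher and 533 to 2014 lower in PG9VN against WT, 102 to 620 and 6 to 269 in PG9V against WT, 16 to 746 and 2 to 374 in PG9VN against PG9V, and 1114 to 3476 among the 3 genotypes. In each of these the highest count came without PG9VN replicate 2.

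The overlap of PG9V and PG9VN calls was 718 with DESeq2 and 102 at an adjusted p of 0.01, against 304. Gene list calls numbered 64 to 75 without 1 library against 65, and 0 with an estimated correlation, as did Reactome calls. The values of Nnt, PG9V against WT (10.43), and Vps13c, PG9VN against WT (2.98), had the opposite sign where transcripts were not summed, each being the value of a single transcript. With 0 counts in every WT library, the Nnt transcript (ENSMUST00000069902.12) has no measurable fold change, and 10.43 gives its direction only. That transcript stood at 5.79 ± 2.37 CPM in PG9V. Of 391 values of named genes, 0 others reversed; the call was lost for 84 with only libraries with Y-linked counts, 109 without summing, 28 with the Y-linked covariate, 41 with only the 2 genotypes, 90 at an adjusted p of 0.01, 6 with limma-voom and 6 with upper-quartile scaling. Without 1 library it was lost for 11 (PG9VN replicate 2) to 71 (PG9V replicate 1). Upper-quartile scaling put 69.1% of the PG9VN against WT calls higher, against 61.4%, and under no scaling was the median log2 fold change of all genes above 0.041, against 0.017. At this depth and with 3 libraries per genotype, 19.4% of simulated 1.5-fold changes were recovered. That share holds for the simulated number of changed genes. The limits set by depth, library number and spread were not separated.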

Other observations

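The leave-one-out counts of gene lists were chosen only after the result was seen; the other tests of this part were planned. Some genes of the cytokine, complement and microglia lists were also higher in comparisons not yet described for these lists. Of the cytokines, chemokines and innate receptors 8 of 33 were higher in PG9V than in WT (18 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation), with 5, 3 and 3 without WT replicate 1, 2 or 3, 4 without PG9V replicate 1 and 3 without PG9V replicate 2. In PG9VN against PG9V 12 of 33 were higher (24 adjusted over the list alone; adjusted p = 0.105 with an estimated correlation), with 0 without PG9V replicate 1 or PG9V replicate 3, 6 without PG9V replicate 2, 7 without WT replicate 3 and 1 without PG9VN replicate 3. Of 22 complement genes 10 were higher there (17 and 1 lower adjusted over the list alone; adjusted p = 0.114 with an estimated correlation), with 3, 3 and 5 without PG9V replicate 1, PG9V replicate 3 or PG9VN replicate 3. Markers of microglia and macrophages were higher in 10 of 17 in PG9V against WT (5 without WT replicate 2, 6 without WT replicate 3) and in 10 of 17 in PG9VN against PG9V (0 without PG9V replicate 1, PG9V replicate 3 or PG9VN replicate 3), with 12 higher and 1 lower, and 12 higher, adjusted over the list alone, and adjusted p = 0.114 and 0.117 with an estimated correlation.

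Of the serotonergic and dopaminergic neuron markers 3 of 6 and 1 of 19 were lower in PG9VN than in WT. The 3 were Gata3, given above as a marker of midbrain neurons, Gata2 and Slc6a4. A different cut of the tissue was not tested for either list. The 6 serotonergic genes had a median of -1.77 against WT (3 lower, 4 adjusted over the list alone; adjusted p = 0.343 with an estimated correlation), and the count of 3 became 1 without WT replicate 1, WT replicate 3, PG9V replicate 1 or any PG9VN library. One of the 3, the serotonin transporter Slc6a4, was at 2.42, 0.677 and 19.4 CPM in the WT libraries and at 0.071 ± 0.034 in PG9VN, near the floor of 3 counts (adjusted p = 0.0476 by edgeR; 0.149 without WT replicate 3). The 19 dopaminergic genes had a median of -1.18, with library means of -0.34, -2.76 and -1.84 in PG9VN replicates 1, 2 and 3. Of these, 1 passed by edgeR (0 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation), while 9 were lower at an unadjusted p under 0.05, 7 were called by DESeq2 and 3 by edgeR with DESeq2 size factors. The edgeR count was 12 without PG9VN replicate 1 and 0 without any other library except WT replicate 2.

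The remaining lists held few calls in PG9VN against WT, and no statement rests on these counts, since most fall to 0 or move by more than 1.5 times without at least 1 library. Genes called higher numbered 5 of 20 for the vacuolar ATPase (5 adjusted over the list alone), 4 of 13 for oligodendrocyte precursors (4), 2 of 17 for choroid plexus and ependyma (2), 1 of 12 for blood (1), 2 of 13 for mitochondrially encoded genes (3), 1 of 20 for immediate-early genes (1) and 1 of 21 for hypothalamic neuropeptides (0), the numbers in parentheses being adjusted over the list alone. Higher and lower genes numbered 6 and 1 of 25 for the unfolded protein and integrated stress response (7 and 3 adjusted over the list alone), 3 and 1 of 17 for endothelium and mural cells (5 and 1), 2 and 1 of 45 for the nuclear respiratory chain (0 and 0), 1 and 3 of 31 for autophagy (1 and 2) and 1 and 2 of 19 for Parkinson disease genes (1 and 3). Among the neighbours of Grn they numbered 4 and 1 of 29 (4 and 1). Of cortex and hippocampus markers 1 of 14 was lower (1 adjusted over the list alone). For oligodendrocyte precursors, blood and mitochondrially encoded genes the adjusted p = 0.392, 0.291 and 0.664 with an estimated correlation.

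Other lists held 0 calls by edgeR in PG9VN against WT. Cholesterol synthesis genes (25) had 2 higher and 3 lower at an unadjusted p under 0.05 and 0 and 2 by DESeq2, and cerebellum markers (10) had 0 and 2 at that p and 0 and 2 by DESeq2. Pituitary genes (3) had 1 and 1 at that p and 0 by DESeq2, while striatum (12), meningeal fibroblast (12) and sex-linked genes (4) had 0 by either. Adjusted over the list alone, 1 pituitary gene was higher and 1 lower, and 0 genes of the other lists passed.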
